A study of Oenococcus oeni
Saccharomyces cerevisiae Vin13 and Saccharomyces cerevisiae Vin13 with 12 samples.

How the data were processed

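The data were 12 arrays of the Affymetrix 3' expression type for yeast, from 4 groups of 3 biological replicates as labelled. The groups were yeast-only and mixed cultures of *S. cerevisiae* VIN13 in synthetic wine must, sampled on days 3 and 7. Per the labels' protocols, yeast was inoculated at an OD600 of 0.1, RNA was extracted with hot phenol, biotin-labelled cRNA was made from 100 ng of total RNA, and 7.5 µg of it was the amount stated for hybridisation. Mixed cultures also held *Oenococcus oeni*, so total RNA from them could include bacterial RNA.

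The deposited values are intensity values on a linear scale, from 5.33 to 44019. Per the submitters' processing notes, they were made with Affymetrix Expression Console and RMA, a method that corrects the background, equalises the distributions of the arrays and summarises the probes of each probe set. No version was given in the sources used here. Since RMA makes the distributions alike, a change that moved most transcripts in one direction would be removed by it, and differences are relative to the rest of the array. The median log2 intensity of the tested probe sets ranged from 6.96 to 7.25 between arrays.

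From there, log2 was taken of the intensities. The design had assumed that the values would already be on the log2 scale, and this step was added when they were not. Probe sets whose ID starts with letters were treated as controls (213), and the other 10715 were tested. No column was left unused. The table that pairs probe sets with genes lists 1 probe set, and the other 10714 tested probe sets are unnamed here. The gene table given covers *O. oeni* and was not used. For this reason 49 gene lists set before the data were examined could not be tested, since the named genes put at most 1 member into any list and at least 4 were required. For the same reason *S. pombe* probe sets could not be removed, and the average over probe sets of a gene could not be tried for the tested probe sets. The value of each of the 8 genes spelled out in the IDs of *S. cerevisiae* control probe sets was the mean log2 intensity of its probe sets, 25 in all. Poly-A spikes (12 probe sets), hybridisation controls bioB, bioC and bioD (7), the control cre (2), ribosomal RNA (7), *S. pombe* messenger controls (22) and synthetic tag controls (17) were averaged per array.

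Comparisons used limma 3.58.1 in R 4.3.3, with lmFit on the 4 group means of all 12 arrays, contrasts, and eBayes without trend or robust options. The residual degrees of freedom were 8 and the prior degrees of freedom 5.55. P-values are two-sided and Benjamini-Hochberg adjusted, with a threshold of 0.05, and counts at 2-fold or more are given beside. The 8 named genes were added as rows to the 10715 probe sets for their own fit of 10723 values. The contrasts were mixed against yeast-only on each day and on their mean, day 7 against day 3 in each culture, and the difference of the culture effect between the days. Groups of control probe sets were compared on their mean per array with two-sided exact permutation tests and 95% intervals from the pooled spread. With 3 arrays against 3 the smallest p is 0.1, and with both days or cultures used it is 0.005. Principal components and correlations between arrays used the 5409 probe sets whose mean lay above the gap between the peaks, at a log2 intensity of 6.88.

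The rule for items named in the text was to take the largest rises and falls of each comparison past the threshold, with no overlap between the replicates. For unnamed probe sets it was limited to 4 IDs, the largest rise and fall of the culture comparison on each day. The 8 control genes and the groups of control probe sets were added after the files were seen.

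Alternatives chosen before the data were examined were to include the controls in the fit, filter dim probe sets at the 25th percentile, apply quantile normalization again, centre each array on its median, use eBayes with trend and robust options, use an ordinary two-sample test of the 6 arrays compared (or, for the mean and the difference between the days, the fit without the empirical Bayes step), weight the arrays, fit only the arrays compared, add the replicate number as a block across all groups or, within each culture, as a random block, leave out each array in turn, and use stricter thresholds. Chosen after seeing the data were the fit of 12 arrays without the empirical Bayes step for the single comparisons, a fit of the bright probe sets alone, quantile normalization over these, and scaling to the poly-A spikes. The fit was tested on simulated data with the means and spreads of the real probe sets. Among 10715 simulated probe sets, 200 were changed on day 7 between the cultures, all drawn from the bright ones. The simulated noise was independent between arrays and equally wide in all groups. The recovery therefore does not cover dim probe sets, deviations shared between arrays or arrays of uneven quality. The fit recovered 86.6% of those changed by 0.5 on the log2 scale, 97.0% of those changed by 1 and 66 of 66 changed by 2, with 11 false calls. Arrays give no depth in the sense of counts, and the number of arrays limits the precision.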

Results

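Transcript levels of the industrial wine yeast *Saccharomyces cerevisiae* VIN13 were measured in synthetic wine must, a defined medium that stands in for grape juice. The yeast was grown either alone (yeast-only culture) or together with *Oenococcus oeni*, the lactic acid bacterium that converts malic acid to lactic acid in wine (mixed culture). The labels name the bacterial strain S6 in the series title and in the sample descriptions, and S5 in the design text, so the strain is not settled here. Yeast was sampled on day 3, in exponential growth, and on day 7, in early stationary phase. The data comprised 12 Affymetrix arrays in 4 groups of 3, labelled as biological replicates. The comparisons addressed how the yeast transcriptome differed in the presence of the bacterium at each day, and how it changed between the days in each culture. Of 10928 probe sets, 213 were controls and 10715 were tested. Their mean log2 intensities formed 2 separate peaks, and 5409 probe sets lay in the bright peak. The platform also carries probe sets for another yeast, *Schizosaccharomyces pombe*, and 19 of its 22 messenger controls lay in the dim peak. The other 3, all for GPD3, lay above the gap, at up to a mean log2 intensity of 9.93.

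The tested probe sets are not paired with gene names in the tables used here, apart from 1 dim probe set listed as ppk1 with a mean log2 intensity of 4.57. Gene names were therefore available for the 8 *S. cerevisiae* genes that the control probe sets spell out, each measured by 3 or 4 probe sets, and for the ribosomal RNAs. All 8 genes are reported, as a group chosen after the files were seen. Of the tested probe sets, 4 are given by their IDs, the largest rise and the largest fall between the cultures on each day among calls whose replicates did not overlap. The arrays limit the precision through their number, 3 per group.

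Arrays of the same group were close to each other, with correlations across the bright probe sets between 0.979 and 0.997. Arrays of the same day from different cultures lay between 0.970 and 0.996, and arrays of different days between 0.854 and 0.912. The first principal component held 86.6% of the variance of the bright probe sets and separated the days. The second held 6.50% and separated the cultures on day 7, where the mixed arrays scored between 5.57 and 13.1 and the yeast-only arrays between -15.7 and -3.72. Yeast-only day 7 replicate 2 stood apart from the other arrays of its day on the first component, at 21.0.

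**Figure D1:**
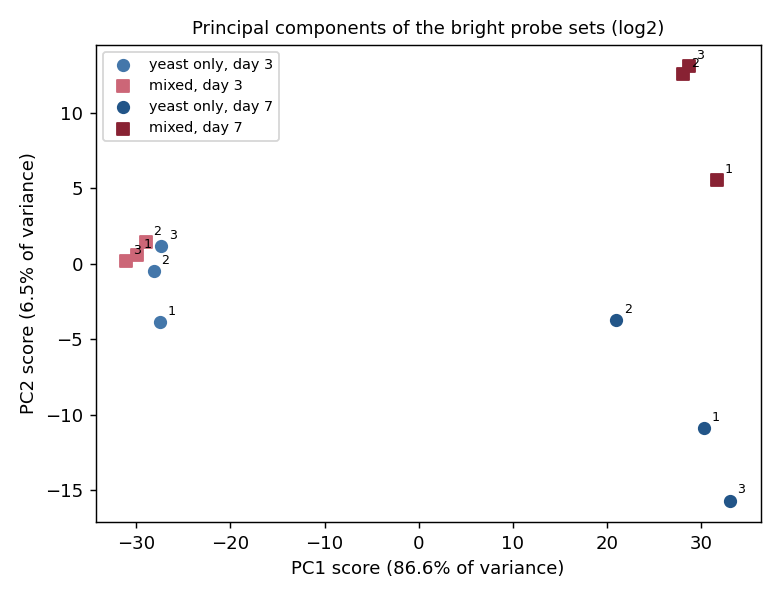
Scores of the 12 arrays on the first and second principal components of the log2 intensities of the bright probe sets, with the replicate number beside each point. The day 7 arrays lie at 21.0 or above on the first component and the day 3 arrays at -27.3 or below, and the cultures separate on the second component on day 7.

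The first comparison asked how yeast grown with *O. oeni* differed from yeast grown alone on day 3. None of the 8 named genes differed between the cultures in limma's moderated test, over all 10723 values tested or adjusted over the list alone. *RIP1*, which encodes the Rieske iron-sulfur protein of respiratory complex III, stood at a log2 intensity of 11.32 ± 0.11 (SD, n = 3) in the mixed culture and 11.51 ± 0.23 in the yeast-only culture. *SRB4*, a subunit of the Mediator complex that links transcription factors to RNA polymerase II, had the smallest p among them, with a difference of -0.26 (SE 0.095) and an adjusted p = 0.464. Its probe sets gave -0.033 at the 3' end of the transcript, -0.28 in the middle and -0.47 at the 5' end. The median culture effect on the difference between 3' and 5' probe sets of the 8 genes was 0.12 on day 3, and was not tested. *ACT1* (actin) differed by -0.11 and *TDH1*, an isozyme of the glycolytic enzyme glyceraldehyde-3-phosphate dehydrogenase, by -0.0013.

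In all, 23 probe sets differed on day 3, 4 of them higher and 19 lower in the mixed culture, and 1 differed by at least 2-fold. That probe set, 1779784_at, had a log2 intensity of 12.10 ± 0.18 in the mixed culture and 9.52 ± 0.66 in the yeast-only culture (SD, n = 3). The difference was 2.58 (SE 0.24), or 5.97-fold, with limma adjusted p = 0.00048. In an ordinary two-sample test of the 6 day 3 arrays its adjusted p was 0.344, the highest of its alternatives. The lowest, 1.48e-33, came after scaling to the poly-A spikes, and the others started at 5.1e-06. That scaling moves all probe sets of an array together, so its very small values are not read as stronger evidence. The probe set with the largest fall whose replicates did not overlap, 1776596_at, stood at 10.39 ± 0.31 in the mixed culture and 11.35 ± 0.24 in the yeast-only culture, a change of -0.97 (SE 0.17, limma adjusted p = 0.0251). This second call ended without mixed replicate 1 or 2 or yeast-only replicate 1 or 3, with only the 6 arrays of day 3, after another quantile normalization and in both tests without the empirical Bayes step, where its adjusted p lay between 0.0535 and 0.458. Over all its alternatives the adjusted p ranged from 3.21e-09, after scaling to the poly-A spikes, to 0.458, and without that scaling from 0.00377. Groups did not overlap for 15.6% of the tested probe sets, where chance gives 10% for 3 arrays against 3. The count of 23 fell to 15 without mixed replicate 1, to 14 without mixed replicate 2, to 13 without the empirical Bayes step in the fit of 12 arrays, and to 0 in the two-sample test, which left 936 probe sets at an unadjusted p under 0.05 (limma 848). Median centring of each array turned its direction, with 173 higher and 14 lower.

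The same comparison on day 7 showed 1 named gene changed. *RIP1* was lower in the mixed culture, at 11.11 ± 0.060 against 12.01 ± 0.26 (SD, n = 3), a log2 difference of -0.90 (SE 0.13) with limma adjusted p = 0.00125, or 9.6e-05 adjusted over the list alone. The mixed culture held 53.7% of the intensity of the yeast-only culture for this gene. Its 3 probe sets gave -0.85, -0.94 and -0.91 from the 3' end through the middle to the 5' end of the transcript. After scaling to the poly-A spikes, control RNAs added to the sample whose amounts are not given in the sources used here, the difference was -0.54. The call ended in an ordinary two-sample test of the 6 day 7 arrays, at adjusted p = 0.138, and the other alternatives gave values from 8.44e-05. The other 7 named genes did not pass the test. *ACT1* differed by -0.0083 (SE 0.080), *WBP1*, a subunit of the oligosaccharyltransferase that attaches sugars to secreted proteins, by -0.017 (SE 0.082), and *SPT15*, the TATA-binding protein, by -0.032 (SE 0.10). *URA3*, which encodes orotidine-5'-phosphate decarboxylase of uracil synthesis, differed by 0.11 (SE 0.094), and *EAF5*, a subunit of the NuA4 histone acetyltransferase, by 0.087 (SE 0.084).

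**Figure D2:**
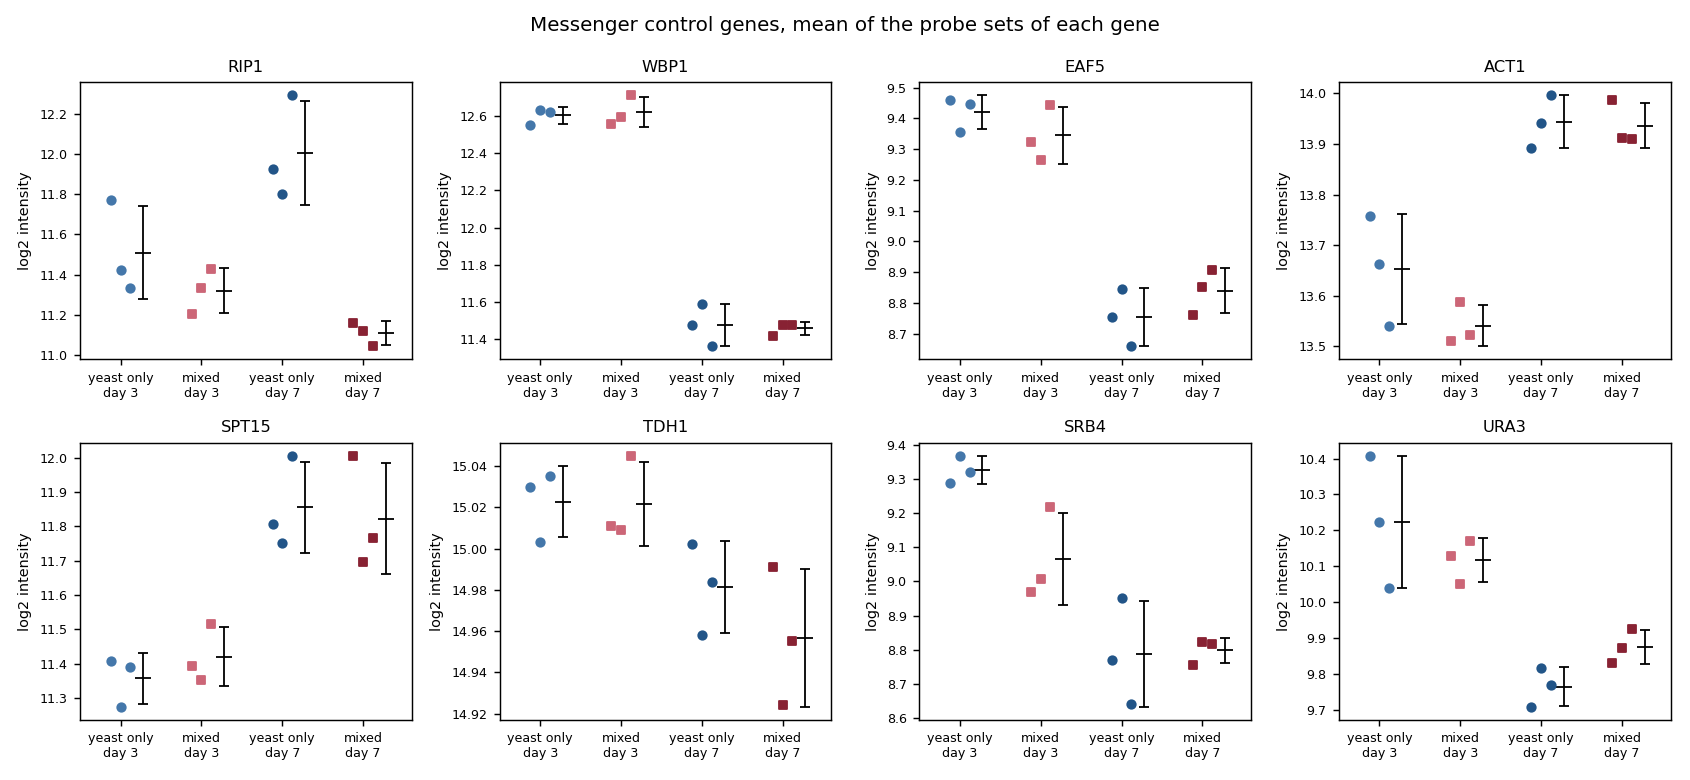
Log2 intensity of the 8 named control genes, as the mean of the probe sets of each gene on each array. Points are arrays, and the bar beside them is the mean with its SD (n = 3). *RIP1* is lower on all 3 mixed arrays of day 7, with a mean of 11.11, than on the yeast-only arrays of that day, with a mean of 12.01. *WBP1* falls by 1.13 and 1.17 between the days in the yeast-only and mixed cultures.

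Among all probe sets, 671 differed between the cultures on day 7, 348 higher and 323 lower in the mixed culture, and 33 of the higher and 46 of the lower differed by at least 2-fold. The largest fall was in 1770785_at, at 6.59 ± 0.41 in the mixed culture and 9.21 ± 0.074 in the yeast-only culture (SD, n = 3). The difference was -2.62 (SE 0.22), or 6.17-fold, with limma adjusted p = 4.76e-05. In the two-sample test its adjusted p was 0.0841, the highest of its alternatives. The largest rise was in 1770303_at, at 9.54 ± 0.51 in the mixed culture and 7.60 ± 1.01 in the yeast-only culture, a difference of 1.94 (SE 0.37, limma adjusted p = 0.0065). Yeast-only replicate 2 read 8.75 for this probe set, and the other yeast-only arrays read 7.09 and 6.94. This call ended with only the 6 arrays of day 7, at adjusted p = 0.0676, without the empirical Bayes step in the fit of 12 arrays, at 0.057, and in the two-sample test, at 0.295. The lowest adjusted p of its alternatives, 3.38e-34, came after scaling to the poly-A spikes, and the others ranged from 7.75e-05 to 0.295. Groups did not overlap for 22.7% of the tested probe sets, against 10% by chance. The count of 671 fell to 315 and 312 without mixed replicate 2 or 3, to 384 and 410 without yeast-only replicate 1 or 3, to 286 with only the arrays of day 7, and to 1 in the two-sample test of these arrays. That test left 1676 probe sets at an unadjusted p under 0.05 (limma 1968). After scaling to the poly-A spikes 4110 were higher and 77 lower.

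**Figure D3:**
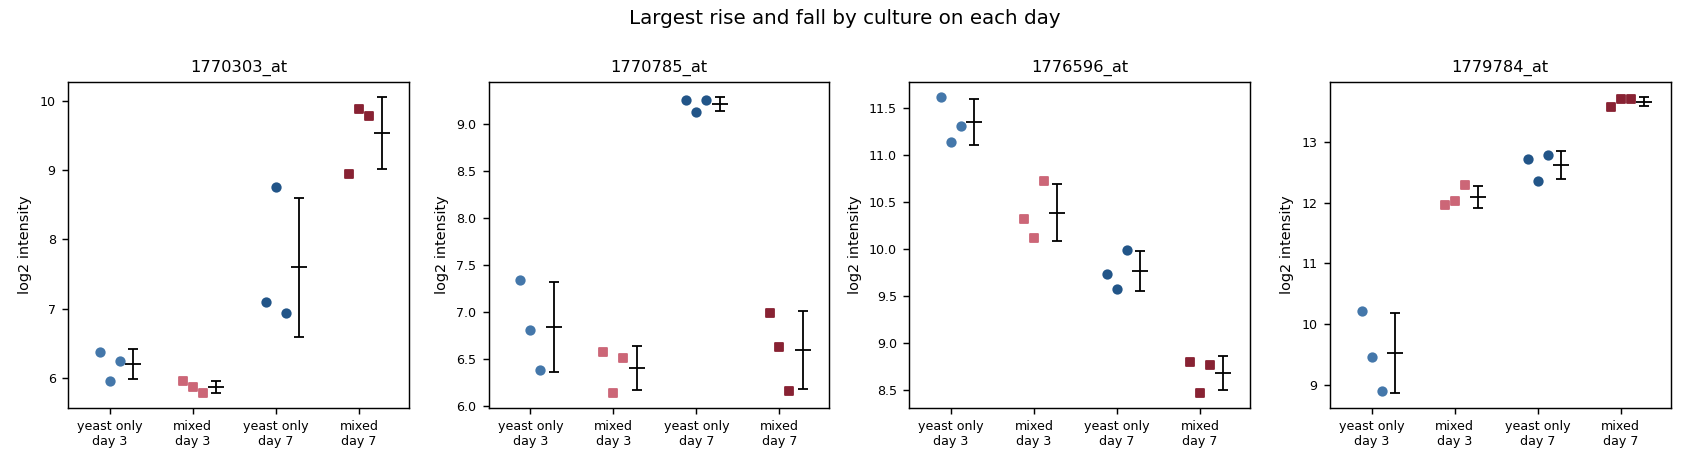
Log2 intensity by group of the 4 probe sets that had the largest rise or fall between the cultures on day 3 or day 7 among calls whose replicates do not overlap. Points are arrays, and the bar beside them is the mean with its SD (n = 3). 1770785_at rises from 6.84 on day 3 to 9.21 on day 7 in the yeast-only culture and reads 6.40 and 6.59 in the mixed culture. 1776596_at reads lower in the mixed culture on both days.

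The probe sets with culture differences on day 7 were also compared between the days. A change over time was common among all bright probe sets, at 70.5% in the yeast-only and 71.2% in the mixed culture. Of the 46 that were lower in the mixed culture, 34 rose and 3 fell from day 3 to day 7 in the yeast-only culture while 14 rose and 12 fell in the mixed culture, with median changes of 1.18 and 0.13. Of all 323 that were lower in the mixed culture, 165 rose and 68 fell in the yeast-only culture, and 78 rose and 147 fell in the mixed culture, with median changes of 0.27 and -0.20. Of the 33 that were higher in the mixed culture, 23 rose and 1 fell in the yeast-only culture and 33 rose in the mixed culture, with median changes of 1.17 and 2.50. Of all 348 that were higher, 141 rose and 103 fell in the yeast-only culture, and 233 rose and 35 fell in the mixed culture, with median changes of 0.10 and 0.60. The difference between the cultures in the change over time passed the test itself for 24 of the 46 and 26 of the 33, and for 66 of the 323 and 95 of the 348. The day 7 arrays enter the choice of these probe sets and each of these comparisons, so part of these numbers may come from the shared arrays. Across the bright probe sets, the covariance of the culture effect on day 7 with the change over time was -0.0223 for the yeast-only culture and 0.0527 for the mixed culture, where simulated arrays without effects gave -0.00708 and 0.00668. The correlations were -0.102 and 0.225, and those of the simulated arrays were larger in size, at -0.542 and 0.509. The simulated noise was equally wide in all groups. The SD of the difference between 2 real day 7 arrays was 0.166 to 0.341 in the yeast-only and 0.134 to 0.204 in the mixed culture. The simulated covariance may thus be too small for the yeast-only culture, and it does not decide how much comes from the shared arrays.

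On the mean of both days, *RIP1* was lower in the mixed culture by a log2 difference of -0.54 (SE 0.095, limma adjusted p = 0.00647). This was the only one of the 8 named genes to pass, also when adjusted over the list alone. The test without the empirical Bayes step gave an adjusted p = 0.0546, and the other alternatives gave values from 0.000741. Across all probe sets, 317 differed, 118 higher and 199 lower, and 16 of them by at least 2-fold. 1779784_at was higher by 1.81 (SE 0.17) and 1776596_at lower, with a difference of -1.03 (SE 0.12), at limma adjusted p = 6.86e-05 and 0.000309. The count fell to between 155 and 200 without mixed day 3 replicate 1 or 2, mixed day 7 replicate 2 or 3, yeast-only day 3 replicate 1 or 2, or yeast-only day 7 replicate 1, and rose to 583 without yeast-only day 7 replicate 2. Median centring turned its direction, with 538 higher and 111 lower.

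Whether the culture effect was alike at both days was tested directly. For *RIP1* the effect on day 7 minus that on day 3 was -0.71 (SE 0.19), with limma adjusted p = 0.0873 over all values and 0.0184 adjusted over the list alone. No other named gene passed, and *ACT1*, *TDH1* and *WBP1* gave 0.10, -0.023 and -0.036. Across all probe sets 172 differed, 102 with a more positive culture effect on day 7 and 70 with a more negative one. 1770785_at was among them, with -2.19 (SE 0.32, limma adjusted p = 0.00712). The count fell to between 76 and 106 without any 1 of the mixed day 3 arrays, mixed day 7 replicate 2 or 3, yeast-only day 3 replicate 2 or yeast-only day 7 replicate 1, and rose to 332 without yeast-only day 7 replicate 2. Median centring turned its direction, with 69 positive and 326 negative, and scaling to the poly-A spikes gave 8107 positive and 22 negative.

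The probe sets called on both days moved the same way. Of the 23 that differed on day 3, 13 also differed on day 7, 4 higher and 9 lower on both. Independent lists drawn from all 10715 probe sets would share 0.130 and 0.573. These expected numbers are too low, since most calls were bright, 18 of the 23 and 589 of the 671. The 2 comparisons share no array, but the fit used the same estimate of spread for both, so the lists are not independent. Over all 10715 probe sets the culture effects of the days correlated weakly across probe sets, which are not independent replicates. Pearson's r was 0.108 (exact permutation p = 0.08 over 400 regroupings within the days) and Spearman's rho was 0.046 (exact permutation p = 0.45). Without yeast-only day 3 replicate 1, Pearson's r was 0.034.

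**Figure D4:**
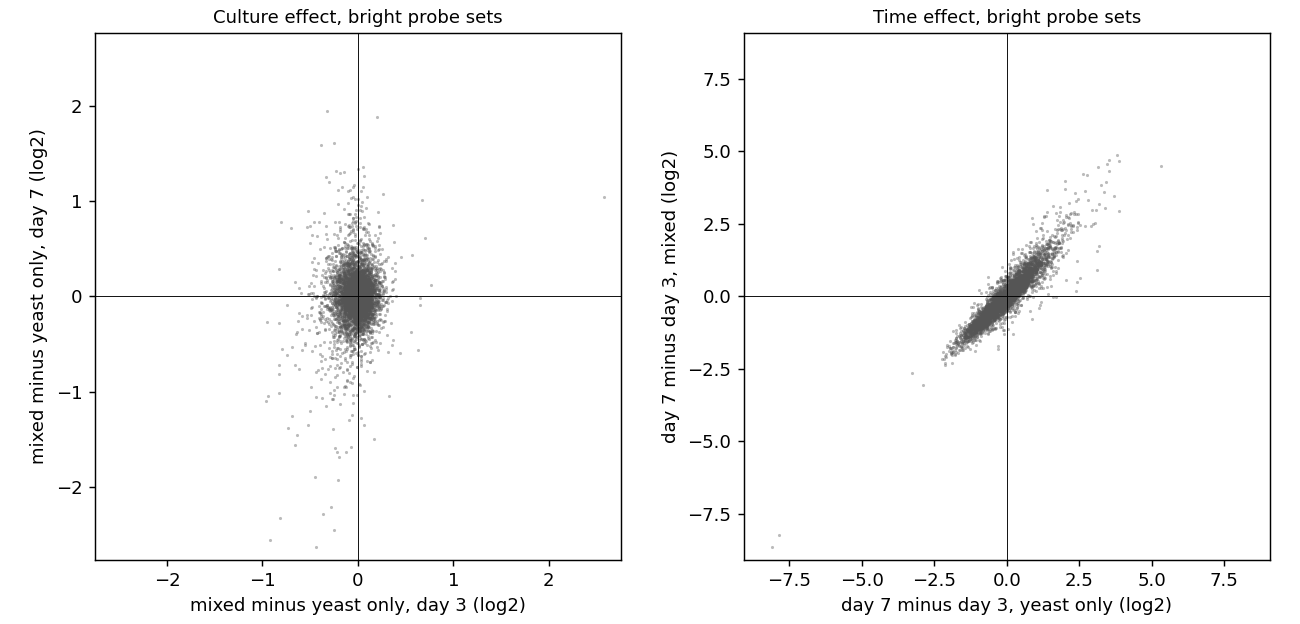
Log2 differences of the bright probe sets, one point per probe set. The left panel sets the culture effect of day 7 against that of day 3, where Pearson's r is 0.147. The exact permutation p of this r is 0.38 over 400 regroupings within the days. The right panel sets the change over time in the mixed culture against that in the yeast-only culture, where r is 0.931.

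The change from exponential to stationary phase was compared within each culture. In the yeast-only culture 7 of the 8 named genes changed. *WBP1* fell by 1.13 (SE 0.082, limma adjusted p = 1.42e-07), *EAF5* fell by 0.67 (SE 0.084, adjusted p = 1.6e-05), *SRB4* fell by 0.54 (SE 0.095) and *URA3* fell by 0.46 (SE 0.094). *SPT15* rose by 0.50 (SE 0.10), *RIP1* by 0.50 (SE 0.13) and *ACT1* by 0.29 (SE 0.080), relative to the array as normalized. Scaling to the poly-A spikes shifts all changes in this culture by one amount, and it turned these 3 rises into falls, with changes of -0.53, -0.53 and -0.73. The spikes rose by 1.02 here. The hybridisation controls bioB, bioC and bioD also rose, by 0.42 in this culture and 0.20 in the mixed culture, and cre changed by 0.070 and -0.012. Part of the spike rise may therefore come from hybridisation, and the scaling does not separate this. The *RIP1* call also ended in the two-sample test, at adjusted p = 0.159, and its alternatives ranged from 0.00132 to 0.159. *TDH1* differed by -0.042 and was close to the top of the measured range, at 15.02 on day 3.

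The fall of *WBP1* was seen in all 3 of its probe sets, by changes of -0.80, -1.17 and -1.42 from the 3' to the 5' end. The probe sets of *SRB4* and *URA3* disagreed. At the 3' end their changes in the yeast-only culture were -0.083 and -0.036, and at the 5' end they were -0.98 and -0.75. The signal of the ribosomal RNAs, which lack the poly-A tail of messenger RNA, was higher on day 7 over the 7 probe sets. Their mean log2 intensity was 12.03 ± 0.26 on day 3 and 14.30 ± 0.13 on day 7 (SD, n = 3). The difference between 3' and 5' probe sets of the messenger controls grew between the days for 5 of the 8 genes, with a median change of 0.19 averaged over the cultures. In the yeast-only culture this difference grew by 0.90 for *SRB4*, 0.71 for *URA3*, 0.62 for *WBP1* and 0.37 for *EAF5*. All of these were called lower on day 7. For the others it changed by -0.023 (*ACT1*), -0.0075 (*RIP1*), -0.038 (*SPT15*) and 0.055 (*TDH1*). The *EAF5* probe sets changed by -0.48, -0.66 and -0.86 from the 3' to the 5' end.

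Across all probe sets, 4267 changed between the days in the yeast-only culture, 1906 higher and 2361 lower on day 7, with 467 in each direction at 2-fold or more. Among the bright probe sets 70.5% changed. The measured changes ran from -8.09 to 5.31. After scaling to the poly-A spikes 236 were higher and 9872 lower, the median change of the bright probe sets moved from -0.089 to -1.11, and dim probe sets were carried along with it.

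In the mixed culture 5 of the 8 named genes changed. *WBP1* fell by 1.17 (SE 0.082, limma adjusted p = 7.12e-08), *EAF5* fell by 0.50 (SE 0.084, adjusted p = 0.000183) and *SRB4* fell by 0.27 (SE 0.095, adjusted p = 0.0367). *ACT1* rose by 0.40 (SE 0.080) and *SPT15* by 0.40 (SE 0.10), relative to the array as normalized. After scaling to the poly-A spikes these rises were 0.029 and 0.036, and after median centring 0.21 each, and neither scaling left them past the threshold. The *SPT15* call also ended in the two-sample test, at adjusted p = 0.0503, and its alternatives ranged from 0.00124 to 0.858. *RIP1* differed by -0.21 (SE 0.13, adjusted p = 0.252) and *URA3* by -0.24 (SE 0.094, adjusted p = 0.0554, or 0.03 adjusted over the list alone). In the mixed culture the *SRB4* probe sets disagreed too, with 0.039 at the 3' end, -0.37 in the middle and -0.47 at the 5' end. The *SRB4* call ended in the two-sample test and without mixed day 3 replicate 3 or any 1 of the mixed day 7 arrays, at adjusted p from 0.0688 to 0.162, and over all alternatives it ranged from 0.000941 to 0.162.

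The ribosomal RNA signal of the mixed culture went from 11.89 ± 0.026 to 14.31 ± 0.073 (SD, n = 3). Over both cultures the change was 2.35 (SE 0.087, exact permutation p = 0.005, the smallest that 400 regroupings within the cultures can give, and 0.03 after adjustment over 18 tests of control groups). All 6 day 7 arrays lay above all 6 day 3 arrays. The 3' probe set of 18S rRNA changed by 4.12 in the yeast-only and 4.48 in the mixed culture, and the 5' probe set, with a mean log2 intensity of 14.91, by 0.15 and 0.26. The culture made a difference of -0.066 to the ribosomal RNA signal on the mean of both days, with a 95% interval from -0.27 to 0.13.

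**Figure D5:**
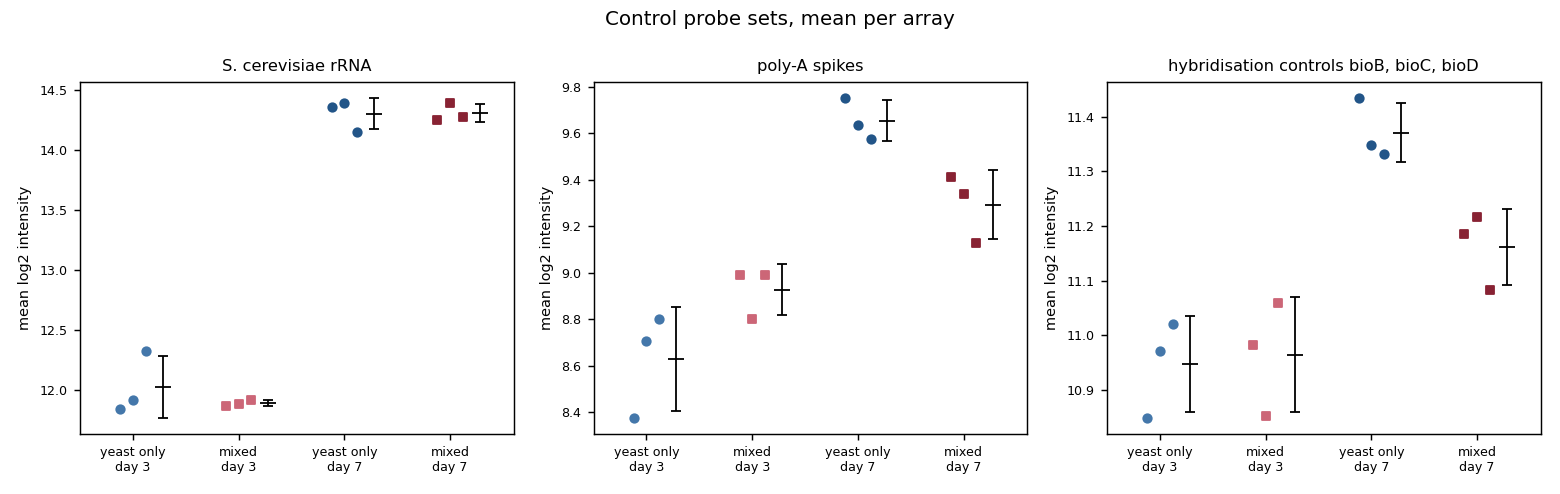
Mean log2 intensity per array of the ribosomal RNA probe sets, the poly-A spikes and the hybridisation controls bioB, bioC and bioD. Points are arrays, and the bar beside them is the mean with its SD (n = 3). The ribosomal RNA signal of the yeast-only culture is 12.03 on day 3 and 14.30 on day 7. The poly-A spikes read higher in the mixed than in the yeast-only culture on day 3 (8.93 against 8.63) and lower on day 7 (9.29 against 9.65).

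Across all probe sets 4293 changed between the days in the mixed culture, 1929 higher and 2364 lower on day 7, with 554 and 461 at 2-fold or more. The changes over time of the cultures, which share no array, correlated across all probe sets with r = 0.905 and a slope of 0.962 of the mixed on the yeast-only change. Of the probe sets called in both cultures, 3426 of 3447 moved the same way, 1488 higher and 1938 lower. Independent lists drawn from all probe sets, bright and dim, would share 343 and 521. These expected numbers are too low, since most calls were bright and the fit used the same estimate of spread for both lists. Median centring left 1298 higher and 3825 lower, and scaling to the poly-A spikes 812 higher and 5116 lower.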

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

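The tests of the poly-A spikes were chosen after their result was seen, and those of the culture effect on day 7 and of the other splits were set before.

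The culture effect differed between the days for 172 probe sets by a direct test of the difference (limma, adjusted p under 0.05). Of 100 splits drawn within the days, 2 gave as many, the real one and one with 317, in which the cultures were exchanged on 1 day so that the contrast became the mean culture effect. Such splits assume that the culture had no effect on either day. They do not test an equal effect on both days, so they cannot decide whether the effect differed between the days. For the mean of both days the real split gave 317, and the highest other of the 100 drawn gave 219. There 1 split, the real one, gave as many, which argues against a chance split at the 0.05 level.

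Of the probe sets given by ID, 3 met the same test of the difference. The culture effect on day 7 minus that on day 3 was -1.53 for 1779784_at, 2.27 for 1770303_at and -2.19 for 1770785_at. The first of these calls ended in 12 of its 21 alternatives and the second in 13, while the third ended in 1, the fit without the empirical Bayes step, at adjusted p = 0.06. The limma adjusted p of the first was 0.0527 with the replicate number as a block. Over all alternatives the adjusted p ranged from 0.00299 to 0.151 for the first and from 3.35e-27 to 0.176 for the second. Both of these lowest values came after scaling to the poly-A spikes, which moves all probe sets of an array together. For the third it ranged from 1.81e-07 to 0.06.

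The single comparisons make 10 splits of 6 arrays each, which are too few for a share under 0.05. On day 3 the real split gave 23 and the highest other 0, and on day 7 the real split gave 671 and the highest other 3. For the time comparisons the real splits gave 4267 in the yeast-only and 4293 in the mixed culture, and the highest other splits 0 in each. In each of these 4 comparisons 1 split, the real one, gave as many.

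For the culture effect on day 7, a difference in how far the fermentations had progressed would place the culture effect along the change over time. With disjoint arrays for both, the correlation across bright probe sets ranged from -0.101 to 0.225 over 9 choices, with a median of 0.0692. Some choices passed 0.2, the bound set beforehand for excluding this, and all 9 lay under 0.5, the bound for it, so part of the effect may lie along the time axis. Bacterial RNA on the array could raise dim probe sets in the mixed culture, and 52.4% of the 82 dim probe sets called were higher there, which leaves this undecided between the bounds set beforehand. Yeast-only replicate 2 stood apart, but without it the count rose to 941, and the lowest count was 312 without mixed replicate 3. The count also fell to 315 without mixed replicate 2 and to 384 and 410 without yeast-only replicate 1 or 3. Leaving out an array also leaves fewer replicates, so these fits cannot tell dependence on a single array from lost precision. The presence of the bacterium remains open as the biological explanation, with *RIP1* lower in the mixed culture by a log2 difference of -0.90.

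The poly-A spikes changed with culture in opposite directions on the days. The culture effect on day 7 minus that on day 3 was -0.66 (exact permutation p = 0.01, or 0.045 adjusted over 18 tests), with 0.30 on day 3 and -0.36 on day 7. The regroupings within the days assume no culture effect on either day, so this p does not test an equal effect on both. The 95% interval of the -0.66, from the pooled spread, was -1.06 to -0.26. Taken alone, the days gave exact permutation p = 0.2 on day 3 and 0.1 on day 7, where 0.1 is the smallest possible. Brighter hybridisation alone, if it shifted spikes and hybridisation controls alike, would leave no culture effect on their difference on either day. The interaction of the spikes minus that of the hybridisation controls was -0.43 (exact permutation p = 0.005, the smallest these regroupings can give). This argues against brightness as the whole cause. Bacterial RNA taking a share of the total RNA would raise the spikes in the mixed culture. On day 7 the spikes were lower, by a difference of -0.36 with a 95% interval from -0.65 to -0.076. The hybridisation controls were lower there too, by a difference of -0.21 (interval from -0.36 to -0.056). Unequal spiking could also hide a rise, so the spikes do not decide on bacterial RNA on day 7. On day 3 the spikes were higher by 0.30 (interval from 0.013 to 0.58), where bacterial RNA may contribute. It cannot be told apart from unequal spiking or a lower messenger share, as the amounts of spike and of bacterial RNA are not given here.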

How the results depend on the processing

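The fit of the bright probe sets, quantile normalization over them, scaling to the poly-A spikes and, for single comparisons, the fit of 12 arrays without the empirical Bayes step were chosen after seeing the data. The 5306 dim probe sets have a median log2 intensity near 3.5, close to background, so changes among them are compressed, and the median of all tested probe sets lies between the peaks, which makes median centring depend on the share of dim probe sets. Both time counts stayed within 1.5 times of 4267 and 4293 except where stated, and the cause of the shifts below was not tested unless named.

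Leaving out 1 array gave 14 to 30 probe sets on day 3, 312 to 941 on day 7, 155 to 583 for the mean, 76 to 332 for the difference between the days, and a correlation of the culture effects from 0.034 to 0.151. Median centring gave 187 on day 3, 649 for the mean and 395 for the difference, moving the median culture effect of the bright probe sets on day 3 from -0.013 to 0.17 and the mixed time change from -0.083 to -0.27. Trend and robust options gave 44 on day 3 and 298 for the difference. Without the empirical Bayes step the fit of 12 arrays gave 13 on day 3 (5 higher, 8 lower), 569 on day 7, 162 for the mean and 43 for the difference. An ordinary two-sample test of the 6 arrays compared, with fewer samples as well, gave 0 on day 3 and 1 on day 7. Array weights gave 306, 1161, 958 and 862 in this order, and weighted yeast-only day 7 replicate 2 at 0.317. Fitting only the arrays of day 7, fewer samples, gave 286.

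At an adjusted p of 0.01 the counts were 15 on day 3, 265 on day 7, 122 for the mean and 37 for the difference. With at least 2-fold they were 1, 79, 16 and 59, and 934 and 1015 for the time change of the yeast-only and mixed cultures. The bright probe sets alone, fewer tested, gave 499 for the mean and 379 for the difference, and quantile normalization over them 500 (246 higher, 254 lower) and 375. Quantile normalization again left 5 higher and 11 lower on day 3, and over the bright probe sets 6 and 15.

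Scaling to the poly-A spikes gave 696 on day 3 (2 higher), 4187 on day 7, 187 for the mean, 10108 for yeast-only over time and 8129 for the difference, as it moved the median of the bright probe sets to -0.31, 0.37, 0.032, -1.11 and 0.68. It reversed the time change in the yeast-only culture of *ACT1* (-0.73), *RIP1* (-0.53) and *SPT15* (-0.53). Of 589 alternatives for the called values of named genes and probe sets, 527 kept direction and call, 59 kept the direction without the call and these 3 reversed.

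The replicate number did not pair the arrays throughout, though some same-numbered arrays deviated alike. Between the day 7 cultures their deviations correlated at 0.400 and 0.487 for replicates 1 and 2 and at -0.036 for replicate 3. Between the day 3 cultures the correlations ran from -0.056 to 0.204, and between the days of the yeast-only culture from -0.105 to 0.0369. With the replicate number as a block the counts were 23, 644, 274, 4246, 4279 and 174, for day 3, day 7, the mean, the time change of the yeast-only and mixed cultures and the difference. In this balanced design the block cannot alter the fold changes or their correlation (0.108). With the replicate number within each culture as a random block, an assumed link between the days, they were 23, 670, 314, 4274, 4299 and 176. The gene lists and the average over probe sets of a gene were not run, since the probe sets are unnamed here.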

Other observations

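The tests of the ribosomal RNA signal were chosen after the result was seen. They concern control probe sets and a few extremes that the comparisons do not rest on.

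A pair of probe sets, singled out after their values were seen, went from bright on day 3 to the level of the background on day 7. Both IDs end in _s_at, and whether they report separate transcripts is not known here. Their group means were 11.07 to 12.62 on day 3 and 3.11 to 4.24 on day 7, and the limma adjusted p was at most 7.78e-12 in both cultures. The measured changes ran from -8.64 to -7.86. As the day 7 values lie at the floor of the arrays, these changes are lower bounds on the size of the falls and do not rank them against other probe sets that reached the floor. The cultures differed little for them, by 0.25 and 0.29 on day 3.

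The ribosomal RNA signal rose by 2.35 on the log2 scale from day 3 to day 7 on the mean of both cultures. A lower share of messenger RNA in the total RNA would raise the spikes as much. Yet on this mean the ribosomal RNA rose by 1.65 more than the poly-A spikes (95% interval from 1.47 to 1.83). If equal amounts of spike were added, which is not known here, this argues against that as the whole cause. The excess differed between the cultures. Ribosomal RNA and spikes rose by 2.28 and 1.02 in the yeast-only culture, and by 2.42 and 0.37 in the mixed culture. Degraded RNA on day 7 would widen the gap between 3' and 5' probe sets of messengers. The gap grew for 5 of the 8 named genes, between the bounds set for the test, so degradation may contribute and is not excluded. A change in ribosomal RNA itself between growth phases, such as more priming within it, was not tested.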
